A study of Mus musculus with 6 samples.

How the data were processed

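RNA was measured in 6 mammary tumours of MMTV-PyMT female mice on the FVB background, a transgenic line in which polyoma middle T antigen driven from a mammary promoter gives multifocal mammary carcinoma. There were 3 tumours from mice given DPM at 10 mg/kg and 3 from mice given vehicle, each described by the labels as a biological replicate. The labels give the drug only as DPM. It is read here as dipyridamole, an inhibitor of nucleoside transport and of cyclic nucleotide phosphodiesterases, from knowledge of the study. Per the labels' protocols, total RNA came from solid, non-necrotic tumour tissue, and 100 ng was labelled with biotin by the standard Affymetrix procedure.

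The deposited table holds one intensity per probe set and array for 35556 probe sets. The intensities are on a linear scale, 1 colour, rounded to whole numbers and never negative. How the authors corrected background, summarised probes or scaled the arrays is not given in the sources used here. The deposited columns had not been equalised between arrays: their medians ran from 270 to 301 and their upper quartiles from 717 to 887. No detection calls or background levels were used here, so no gene is called absent.

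Intensities were floored at 1, taken to log2 and quantile-normalised over all probe sets, as the design fixed for a table whose quantiles differ between arrays. Probe sets were named through GEO's platform annotation: 21789 named 1 gene, 1621 named several and were left out, and 12146 were not listed there and are unnamed here. Symbols were updated through the Entrez identifier for 21698 of the 21789, and 91 kept the annotation's symbol. The 19938 genes were each represented by their probe set with the highest mean over the 6 arrays, 999 genes having more than 1. Genes with a mean below the 25th percentile were then left out (4985), and 14953 were tested. The array's genome build is not given in the sources used here, so no coordinates are printed.

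Differences are DPM minus vehicle on the log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the 14953 genes and a threshold of 0.05. All adjusted p-values of single genes below are from this limma fit. In total 36 gene lists, 19 of pathways and 17 of cell type markers, were fixed before the data were examined. The 33 lists with at least 5 genes measured were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 33. The camera test with a correlation estimated per list, and the rotation test fry, were alternatives. Camera with an estimated correlation also uses the few residual degrees of freedom of 6 arrays, which the preset form does not. List scores are the mean over members of each gene's log2 value minus its mean over the 6 arrays. Members are counted as measured where they passed the filter on mean level. Natural killer cell, mast cell and erythrocyte markers had 3 such members each and were not tested. Without the filter, natural killer and mast cell markers were tested and not called (camera adjusted p = 0.583 and 0.311).

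Genes named in the text were chosen by a rule fixed together with the lists. It takes up to 10 genes per direction past the threshold, filled by the smallest unadjusted p where fewer pass, up to 4 members of each list called, and 10 genes named whatever their value. Of those 10, Adora2a and Adora2b were not analysed here, and 1 is not reported here. Genes outside the rule are marked as chosen after their values were seen.

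Arrays were simulated from the real means of the 14953 genes and their spreads as moderated by limma. On these, the gene test recovered 94 of 100 genes changed by 1 log2 unit and 100 of 100 changed by 2, with 13 false calls. Both sets of 100 were in the same simulated arrays, and an adjusted threshold is easier to pass where many genes change. The counts therefore do not give the share of changed genes that the test would find on the real arrays. Those simulated genes varied independently. In 20 simulated sets with 1 list of 22 genes shifted by 0.3 log2, camera called that list 20 times with the preset and 13 times with the estimated correlation. The preset form called 3 of 640 unshifted lists. Genes varied independently in these sets too, whereas real lists that were called had estimated correlations of up to 0.770. The 3 calls therefore do not give the rate of false calls on the real arrays.

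Other settings were no filter or a filter at the 50th percentile, median centring, the mean of all probe sets of a gene, each probe set tested by itself, eBayes without trend or robust, array weights, 16 added before log2, the replicate number as a block, and each array left out. After the data were seen, 2 were added: no between-array normalisation, and leaving out both arrays numbered 3. The labels name no batch. With 3 arrays per group, the number of arrays limits the precision of every value. No pair of arrays was a duplicate: Pearson's r between arrays over the tested genes ran from 0.968 to 0.987.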

Results

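Gene expression was profiled on 1-colour Affymetrix arrays in 6 mammary tumours, 3 from mice treated with DPM and 3 from vehicle-treated mice. The mice were drawn from arms of 10 DPM-treated and 7 vehicle-treated animals. Dosing began at 4 weeks of age, when hyperplastic lesions start to form in this strain, on a schedule of 5 days with injections and 2 without. It lasted 11 weeks, and tumours were taken at 15 weeks. The comparison asks how RNA levels differed between tumours that had grown under the drug and tumours that had grown under vehicle. Deposited median intensities were 277, 270 and 301 on the DPM arrays and 275, 282 and 300 on the vehicle arrays (replicates 1 to 3). The upper quartiles were 869 and 887 on the arrays numbered 3 of the DPM and vehicle groups, and 717 to 748 on the other 4.

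No single gene passed the threshold between DPM and vehicle tumours. As groups, interferon-stimulated, inflammatory and basal epithelial genes had lower mean levels in DPM tumours, and genes of fatty acid synthesis and of nucleoside handling had higher ones. Camera called these 5 lists with a preset correlation between genes, also with any 1 array left out. It called none with a correlation estimated from the arrays. The preset form also called the interferon list in 4 of the 9 other splits of the arrays, which mix the treatments. It called the fatty acid and inflammatory lists in 2 of these each, and the basal and nucleoside lists in 1 each. The interferon scores overlapped between DPM and vehicle arrays. Keeping a call with 1 array left out does not by itself tie a list to treatment. Another 7 lists, extracellular matrix and milk protein genes among them, were called but lost the call when 1 array was left out. No difference was detectable for Slc29a1, Slc29a2, Pde5a and Pde4d, which encode transporters and phosphodiesterases.

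With all 6 arrays, the arrays of a treatment group were no closer to each other than to those of the other group. Over the 14953 genes tested, the mean distance between arrays of different groups was 32.9 log2 units, against 33.6 between arrays of the same group. The difference of -0.754 had p = 0.8 in a one-sided exact permutation test over the 10 splits of the arrays, which cannot give a p below 0.1. The separation of arrays by treatment was above 0, at 0.161, with the filter at the 50th percentile (p = 0.5 in the exact permutation test), and was 0.948 without DPM replicate 1 and 0.244 without DPM replicate 2. The shortest distance of all, 26.5, lay between DPM replicate 2 and vehicle replicate 1. The first principal component carried 32.9% of the variance, with scores of -8.04, -3.20 and 20.7 on the DPM arrays and -0.845, -18.0 and 9.36 on the vehicle arrays. Its highest scores belonged to the arrays numbered 3, which also had the highest deposited upper quartiles.

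**Figure D1:**
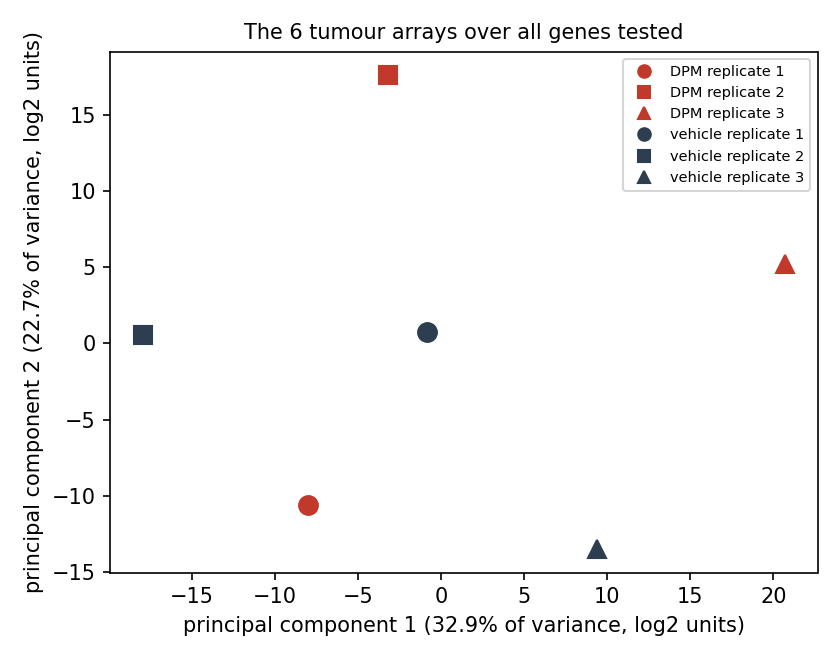
Scores of the 6 arrays on the first principal component (x axis, 32.9% of variance) and the second (y axis, 22.7%), in log2 units over the 14953 genes tested. Colour gives the group and marker shape the replicate number, and the DPM and vehicle arrays are interspersed along both axes.

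The limma fit of DPM against vehicle called 0 of 14953 genes, with a smallest adjusted p of 0.676. At an unadjusted p under 0.05 there were 578 genes, 251 with the higher mean in DPM and 327 with the higher mean in vehicle tumours, where 748 would be expected by chance. The 3 DPM values lay wholly apart from the 3 vehicle values for 1042 genes (6.97%), where chance gives 10%. The 95% interval of the difference lay within 1 log2 unit on either side of 0 for 14637 genes (97.9%), without adjustment for the number of genes. The largest difference of any gene was 1.76 log2 units in size. The median SD within groups was 0.135 log2 units.

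Among genes with lower mean levels in DPM tumours, the smallest p-values belonged to an ion channel, a small heat shock protein and a secreted pattern recognition protein. Trpm6, a magnesium channel (probe set 10461934), averaged 8.41 ± 0.08 in DPM and 9.16 ± 0.13 in vehicle tumours (log2, SD, n = 3 each), a difference of -0.74 (SE 0.10, limma adjusted p = 0.676). Cryab, the alpha-B crystallin chaperone (probe set 10585214), averaged 10.57 ± 0.21 and 11.46 ± 0.14, or 0.537 times the vehicle level. Ptx3, a pentraxin of innate immunity (probe set 10492448), averaged 7.79 ± 0.21 and 8.63 ± 0.10, or 0.557 times. Lgals3bp, which encodes a secreted glycoprotein that binds galectin-3, averaged 11.77 ± 0.16 and 12.48 ± 0.15. The other 6 were the adhesion protein gene Flrt3 (-0.81), the microRNA gene Mir140 (-1.49), Nol11 (-0.69), the sarcoglycan gene Sgce (-0.78), the tubulin gene Tubb2b (-0.76) and Pxdc1 (-0.66, all log2). Mir140 was the dimmest of the 10 in DPM tumours, at 7.25 ± 0.41.

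Among genes with higher mean levels in DPM tumours, Tmc5 (probe set 10556616) had the smallest p. It averaged 9.86 ± 0.05 in DPM and 9.15 ± 0.18 in vehicle tumours, a difference of 0.71 (SE 0.11, n = 3 each, limma adjusted p = 0.676). Gpd1, which makes glycerol-3-phosphate, averaged 10.89 ± 0.06 and 10.28 ± 0.22. The fatty acid transporter gene Slc27a1 averaged 10.83 ± 0.05 and 10.42 ± 0.05. Bhlha15, a transcription factor of secretory cells also called Mist1, averaged 11.09 ± 0.13 and 10.39 ± 0.24, or 1.62 times the vehicle level. The zinc transporter gene Slc30a2 averaged 9.39 ± 0.05 and 8.93 ± 0.12. The other 5 were Dhrs7 (0.60), Rap1gap (0.65), Blnk (0.67), Ttc9 (0.65) and the lipase gene Ddhd2 (0.49, all log2). For all 20 genes of these 2 sets the DPM and vehicle values did not overlap, which is part of how such genes are found, and none passed the threshold (limma adjusted p 0.676 to 0.904).

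**Figure D2:**
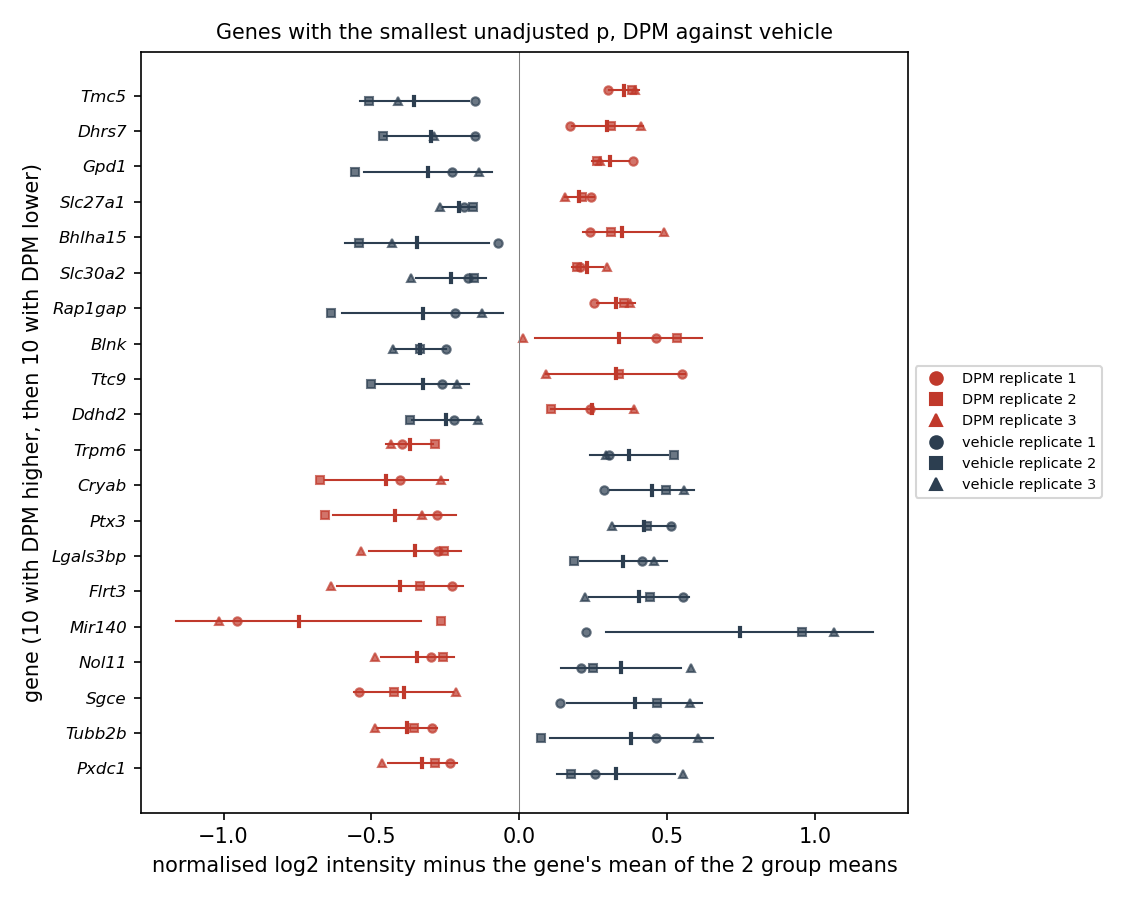
Normalised log2 intensity (x axis) of the 10 genes per direction with the smallest unadjusted p, each shown relative to the midpoint of its DPM and vehicle means. Points are single arrays, ticks are group means and bars are ±1 SD (n = 3), and the DPM and vehicle points are apart for all 20 genes although none passed the adjusted threshold.

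Among the proteins that dipyridamole is known to act on, Slc29a1, the main equilibrative nucleoside transporter, was abundant at 12.14 ± 0.15 in DPM and 12.06 ± 0.13 in vehicle tumours, with a 95% interval of the difference from -0.16 to 0.32 log2. Slc29a2, the second such transporter, averaged 9.21 ± 0.10 and 9.20 ± 0.10, with an interval that ended at 0.23. The phosphodiesterase genes Pde5a and Pde4d differed by -0.08 (SE 0.10) and 0.05 (SE 0.08), and the log2 change of Pde4d was 0.12 as the mean of its 3 probe sets. Pde5a was dimmer than these other genes, at 8.21 ± 0.07 in DPM and 8.29 ± 0.12 in vehicle tumours, and was removed by the filter at the 50th percentile. Ada, adenosine deaminase, differed by 0.23 (SE 0.11, n = 3 each, limma adjusted p = 1). The proliferation marker Mki67 averaged 11.36 ± 0.14 and 11.22 ± 0.27, and the cyclin gene Ccnd1 12.10 ± 0.35 and 12.16 ± 0.24.

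Of the 33 gene lists tested, 12 were called by camera with the preset correlation, 5 toward higher and 7 toward lower levels in DPM tumours. With a correlation estimated from the arrays, and with fry, 0 of the 33 were called, with smallest adjusted p-values of 0.232 and 0.189 and 5 and 3 lists at an unadjusted p under 0.05. Over all genes tested, no member of any list was called. Adjusted over each list alone, with no adjustment across the 33 lists, 5 genes passed, and some would pass by chance. Lower in DPM were Ifit3 and Oas3 among interferon genes, Ptx3 among inflammatory genes and Krt14 among basal markers. Calml3 among squamous markers was higher in DPM and was named after its value was seen. The score of a list did not overlap between DPM and vehicle arrays for 5 of the 33 lists tested, all among the 12 called. Chance gives 10%, and the 12 were called for the same shift. Each of these 5 had p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 arrays can give. Of the 12, 5 were called in all 6 analyses that left out 1 array. Those 5 were the interferon, fatty acid, basal, inflammatory and nucleoside lists.

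**Figure D3:**
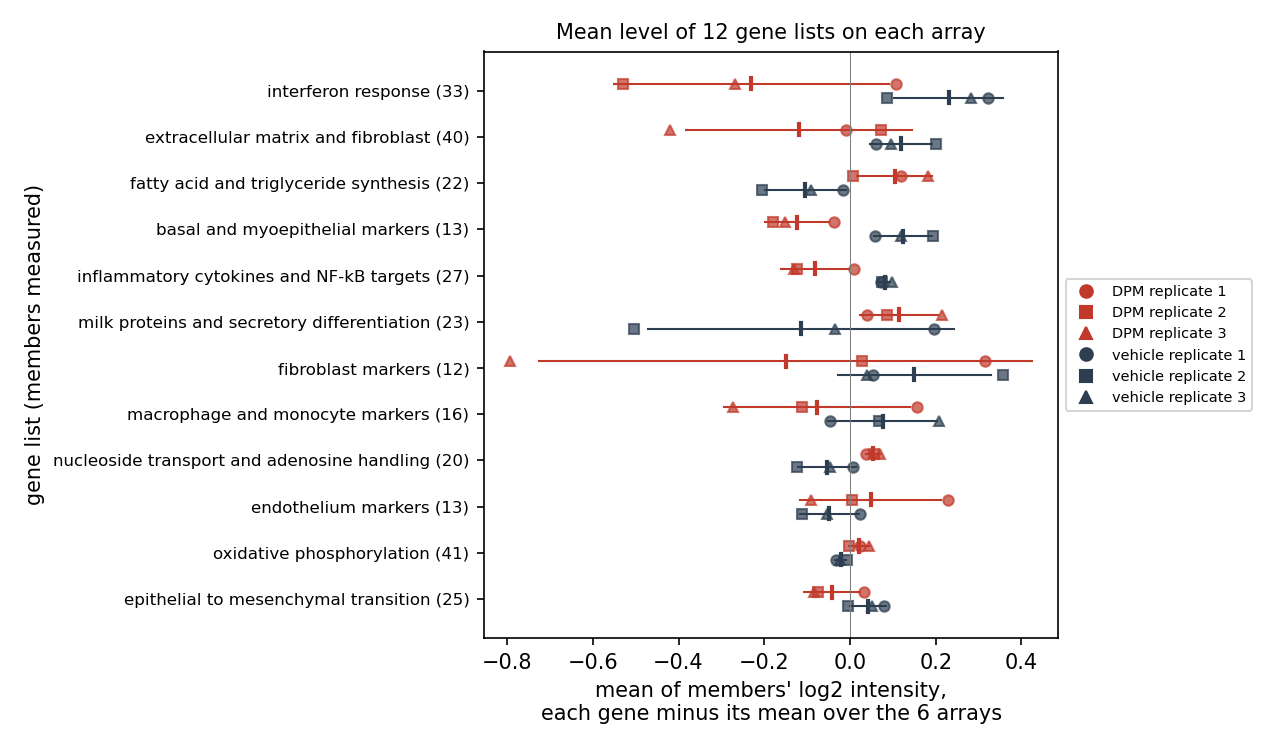
Mean level of the 12 gene lists called with a preset correlation, on each array (x axis, log2 units relative to each gene's mean over the 6 arrays). Points are arrays, ticks are group means and bars are ±1 SD (n = 3). The basal marker scores of the DPM arrays all lie below those of the vehicle arrays, while the fibroblast scores spread from -0.793 to 0.314 within the DPM group alone.

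Interferon-stimulated genes were shifted lower in DPM tumours, with 32 of 33 measured members having the lower mean there. The list averaged a difference of -0.461 log2 (camera adjusted p = 1.16e-25 with the preset correlation, adjusted p = 0.263 with an estimated correlation). Ifit3, an antiviral effector, averaged 9.05 ± 0.57 in DPM and 10.13 ± 0.12 in vehicle tumours. Oasl2 averaged 10.48 ± 0.68 and 11.42 ± 0.04, Oas3 7.99 ± 0.21 and 8.56 ± 0.13, and the chemokine gene Cxcl10 7.60 ± 0.03 and 7.94 ± 0.13. The scores were 0.107, -0.529 and -0.269 on the DPM arrays and 0.323, 0.086 and 0.282 on the vehicle arrays, so that DPM replicate 1 overlapped the vehicle group (exact permutation p = 0.2, two-sided). Dendritic cell markers had a mean difference of -0.149 (camera adjusted p = 0.0802). That list passed with the filter at the 50th percentile (adjusted p = 0.0255), median centring (0.0329), array weights (0.0203) or no between-array normalisation (0.0327), and without DPM replicate 1 (mean -0.272) or vehicle replicate 2 (-0.211). Its mean was -0.0794 without DPM replicate 2, -0.0950 without DPM replicate 3, -0.0765 without vehicle replicate 3 and -0.0231 without both arrays numbered 3, none of them called. Macrophage and monocyte markers were shifted lower by -0.153 (camera adjusted p = 0.000554, adjusted p = 0.606 with an estimated correlation), with 14 of 16 lower. The complement gene C1qc differed by -0.30 (SE 0.11), Cd14 by -0.31 (SE 0.17), Adgre1 by -0.24 (SE 0.16) and Lyz1, which has a close paralog, by -0.25 (SE 0.16). The macrophage call was lost without DPM replicate 3 (mean -0.0553) or without vehicle replicate 3 (mean -0.0868), and the mean was -0.271 without DPM replicate 1. Without both arrays numbered 3 the macrophage mean was 0.00982 and the list was not called.

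Genes of inflammatory cytokines and NF-kB targets were also shifted lower, with 21 of 27 members lower in DPM tumours and a mean difference of -0.163 (camera adjusted p = 7.3e-05, adjusted p = 0.263 with an estimated correlation). Besides Ptx3, the prostaglandin synthase gene Ptgs2 averaged 8.96 ± 0.41 in DPM and 9.85 ± 0.43 in vehicle tumours. The cytokine gene Lif differed by -0.37 (SE 0.12) and the chemokine gene Ccl3 by -0.46 (SE 0.16). The score was -0.081 ± 0.080 on DPM and 0.081 ± 0.013 on vehicle arrays (n = 3 each), without overlap.

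Basal and myoepithelial markers were lower in DPM tumours for 11 of 13 genes, with a mean difference of -0.247 (camera adjusted p = 1.25e-05, adjusted p = 0.232 with an estimated correlation). Krt14, a basal keratin, averaged 10.03 ± 0.30 in DPM and 10.81 ± 0.15 in vehicle tumours, or 0.585 times the vehicle level. Krt5, its partner keratin, averaged 10.19 ± 0.49 and 10.81 ± 0.28. The collagen gene Col17a1 differed by -0.23 (SE 0.09) and the smooth muscle actin gene Acta2 by -0.25 (SE 0.11). Luminal markers gave a mean difference of -0.017 (camera adjusted p = 0.955). The epithelial to mesenchymal transition list, which mixes epithelial and mesenchymal genes, had 19 of 25 members lower and a mean difference of -0.084 (camera adjusted p = 0.0461, adjusted p = 0.519 with an estimated correlation). Its leading members were the mesenchymal genes Snai2 (-0.30, SE 0.08), Vim (-0.32, SE 0.12) and Cdh2 (-0.53, SE 0.25), and the epithelial claudin gene Cldn4 at 0.18 (SE 0.10). That call was lost when DPM replicate 2 (mean -0.0676), DPM replicate 3 (-0.0631), vehicle replicate 1 (-0.0652) or vehicle replicate 3 (-0.0784) was left out. It was also lost with the filter at the 50th percentile (adjusted p = 0.0838), with median centring (0.0529) and without an intensity trend (0.05). Leaving out both arrays numbered 3 lost it too (mean -0.0573, camera adjusted p = 0.162).

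Extracellular matrix and fibroblast genes were lower in DPM tumours for 35 of 40 members, with a mean difference of -0.238 (camera adjusted p = 8.55e-09, adjusted p = 0.567 with an estimated correlation). Without DPM replicate 3 the mean was -0.0822 and the adjusted p 0.074. Without both arrays numbered 3 the mean was -0.0934 and the list was called (adjusted p = 0.0318). Thbs2, a matricellular thrombospondin, averaged 10.30 ± 0.23 in DPM and 10.92 ± 0.21 in vehicle tumours. The metalloproteinase inhibitor gene Timp3 differed by -0.55 (SE 0.17), the collagenase gene Mmp13 by -0.91 (SE 0.30) and the growth factor gene Tgfb2 by 0.28 (SE 0.09). The fibroblast marker list, which shares 8 genes with this one, had 12 of 12 members lower and a mean difference of -0.300 (camera adjusted p = 0.000458, adjusted p = 0.633 with an estimated correlation). Its scores were 0.314, 0.029 and -0.793 on the DPM arrays. Without DPM replicate 3 its mean was 0.0282, without vehicle replicate 2 it was -0.199 and not called, and without DPM replicate 1 it was -0.535. It was -0.191 with array weights (adjusted p = 0.029) and -0.0213 without both arrays numbered 3, where the call was lost. Col1a1 differed by -0.30 (SE 0.21), Col1a2 by -0.32 (SE 0.18), Serpinf1 by -0.30 (SE 0.21) and Pi16 by -0.29 (SE 0.21).

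Genes of fatty acid and triglyceride synthesis were higher in DPM tumours for 18 of 22 members, with a mean difference of 0.207 (camera adjusted p = 4.52e-06, adjusted p = 0.263 with an estimated correlation). Thrsp, a regulator of lipogenesis, averaged 11.06 ± 0.52 in DPM and 10.08 ± 0.07 in vehicle tumours, or 1.96 times the vehicle level. The phosphatidate phosphatase gene Lpin1 averaged 10.05 ± 0.20 and 9.40 ± 0.30. The acetyl-CoA carboxylase gene Acacb differed by 0.57 (SE 0.19), and the desaturase gene Scd1 averaged 13.61 ± 0.28 and 13.16 ± 0.19. Adipocyte marker scores were 1.033, -0.429 and -0.516 on the DPM arrays and 0.315, -0.126 and -0.277 on the vehicle arrays (camera adjusted p = 0.349), with the highest value in DPM replicate 1. That list was called lower in DPM without DPM replicate 1 (mean -0.497, adjusted p = 3.04e-05), and higher without DPM replicate 2 (0.288, adjusted p = 0.0143) or DPM replicate 3 (0.332, adjusted p = 0.00484). Cholesterol synthesis genes had a mean difference of 0.046 (camera adjusted p = 0.135) and were called higher without DPM replicate 2 (0.0886), vehicle replicate 1 (0.0765) or both arrays numbered 3 (0.0808). Their mean was -0.0143 without DPM replicate 1, -0.00253 without vehicle replicate 2 and 0.00561 with array weights, none of them called.

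Milk protein and secretory differentiation genes were higher in DPM tumours for 20 of 23 members, with a mean difference of 0.228 (camera adjusted p = 7.3e-05, adjusted p = 0.567 with an estimated correlation). The lipase gene Cel averaged 9.23 ± 0.29 in DPM and 8.45 ± 0.44 in vehicle tumours. Elf5, a transcription factor of alveolar cells, averaged 12.31 ± 0.07 and 11.99 ± 0.18, and Muc1 differed by 0.38 (SE 0.13). Mfge8, a milk fat globule protein gene, went the other way, at 13.26 ± 0.28 and 13.72 ± 0.04. Vehicle replicate 2 had a score of -0.504, and without it the mean difference was 0.0339 and the call was lost. Without vehicle replicate 1 the mean was 0.379, and with array weights it was 0.10 (adjusted p = 0.0486).

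Nucleoside transport and adenosine handling genes were higher for 16 of 20 members by a mean of 0.108 (camera adjusted p = 0.00391, adjusted p = 0.263 with an estimated correlation). The score was 0.054 ± 0.017 on DPM and -0.054 ± 0.067 on vehicle arrays (n = 3 each). The transporter gene Slc29a3 averaged 11.50 ± 0.21 in DPM and 11.12 ± 0.11 in vehicle tumours. Adk, adenosine kinase, averaged 10.25 ± 0.06 and 9.95 ± 0.15. The ectonucleotidase gene Entpd1 differed by 0.44 (SE 0.19), and Tk1, thymidine kinase, by -0.34 (SE 0.15). Oxidative phosphorylation genes were higher for 32 of 41 members by a mean of 0.043 (camera adjusted p = 0.0277, adjusted p = 0.519 with an estimated correlation). Cox4i1 differed by 0.14 (SE 0.08), Ndufb9 by 0.14 (SE 0.09) and Ndufb8 by 0.10 (SE 0.08). Cycs differed by 0.17 (SE 0.13), and its 3 probe sets did not share a direction. The log2 change of Cycs was 0.07 as their mean. The oxidative phosphorylation call was lost without DPM replicate 1 (mean 0.0425), DPM replicate 3 (0.0318), vehicle replicate 1 (0.0375) or vehicle replicate 3 (0.0425). It was also lost without both arrays numbered 3 (0.0308). Endothelial markers were higher for 11 of 13 by a mean of 0.096 (camera adjusted p = 0.0118, adjusted p = 0.665 with an estimated correlation). Esam differed by 0.24 (SE 0.13), Kdr by 0.20 (SE 0.12), Cdh5 by 0.19 (SE 0.12) and Tie1 by 0.15 (SE 0.10). Without DPM replicate 1 the endothelial mean was 0.0053 and without vehicle replicate 2 it was 0.064, neither called, and without DPM replicate 3 it was 0.164. With array weights the endothelial adjusted p was 0.0692.

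The remaining lists did not pass in the fit reported here. Cell cycle and mitosis genes had 23 of 44 members higher in DPM and a mean difference of -0.002 (camera adjusted p = 0.962). Single vehicle tumours decided that value: without vehicle replicate 1 the list was called lower in DPM (mean -0.0849, adjusted p = 0.0013), and without vehicle replicate 2 it was called higher (0.0880, adjusted p = 0.000553). Mean differences were 0.010 for nucleotide synthesis (adjusted p = 0.773), 0.013 for hypoxia and glycolysis (0.491), 0.056 for phosphodiesterases and cAMP targets (0.156), 0.026 for Wnt targets (0.955) and -0.016 for angiogenesis and platelet genes (0.648). They were -0.050 for p53 targets and apoptosis (0.124), -0.031 for the unfolded protein response (0.218), -0.049 for hormone receptor signalling (0.287) and -0.002 for drug transport (0.914). Among marker lists they were -0.057 for T cells (0.205), -0.054 for B and plasma cells (0.482), 0.014 for neutrophils (0.749), 0.021 for pericytes (0.816), 0.112 for skeletal muscle (0.135), 0.133 for squamous epithelium (0.328) and -0.020 for nerve (0.754). Several of these moved both ways when arrays were left out. Skeletal muscle markers were called higher without DPM replicate 2 (mean 0.198), DPM replicate 3 (0.169), vehicle replicate 3 (0.261) or both arrays numbered 3 (0.314), and their mean was -0.0382 without DPM replicate 1. Squamous markers were called higher without vehicle replicate 3 (0.239) or both arrays numbered 3 (0.297), and their mean was -0.0691 without DPM replicate 1. The phosphodiesterase list was called higher without DPM replicate 3 (0.102, adjusted p = 0.0271) and without both arrays numbered 3 (0.115, adjusted p = 0.011), and its mean was 0.0109 without vehicle replicate 2. Nucleotide synthesis was called higher without vehicle replicate 2 (0.0540), and its mean was below 0 without DPM replicate 3 (-0.0144), vehicle replicate 1 (-0.0114) or vehicle replicate 3 (-0.0128). The p53 list was called lower without DPM replicate 2 (-0.0914) or vehicle replicate 2 (-0.0722), and its mean was 0.0222 without DPM replicate 3 and 0.0313 without both arrays numbered 3. The unfolded protein response was called lower without vehicle replicate 2 (-0.100) or with array weights (-0.0668), and its mean was 0.00892 without vehicle replicate 1. The mean, median and camera direction differed in sign for the nerve, angiogenesis, pericyte, Wnt and cell cycle lists.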

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

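The count of 0 genes held in all 19 other settings, among them the fit with the replicate number as a block (replicate block), each probe set tested, array weights and an adjusted p under 0.10. The count of lists called was 12 with the block too. It was 0 with an estimated correlation and 0 with fry, and 10 to 15 when 1 array was left out. Which lists these were differed: 7 to 11 of the 12 stayed called in the same direction in the 6 such analyses, and 8 of 12 without both arrays numbered 3. The separation of arrays by treatment was 0.161 with the filter at the 50th percentile, against -0.754, and ran from -1.91 to 0.948 when 1 array was left out. Of 1249 values of named genes under other settings, 9 changed sign, in 2 genes that were never called. The log2 change of Slc29a2 ran from -0.036 to 0.066 with 1 array left out and was -0.064 without both arrays numbered 3, against 0.009. The log2 change of Ccnd1 ran from -0.27 to 0.059 and was 0.068, against -0.067. Of 204 values of the 12 lists, all with the preset correlation, 180 kept their call and direction and 23 lost the call. The other 1 turned direction in the test: the macrophage list, with a mean of 0.00982 without both arrays numbered 3. Among the 23, the fibroblast mean changed sign too, to 0.0282 without DPM replicate 3. Of the 21 lists not called, 10 were called in at least 1 of the 6 analyses without 1 array, 2 of them in both directions. Why these values moved was not tested. The count of genes at an unadjusted p under 0.05 was 343 without between-array normalisation and 316 without both arrays numbered 3, against 578. Whether the replicate numbers pair the tumours cannot be decided with 3 arrays per group. Same-numbered arrays deviated from their group means with correlations of -0.12, 0.11 and 0.371. The last, for the arrays numbered 3, was the highest between any DPM and vehicle array. Of the 3 DPM arrays, 1 correlated best with its own number. The block changed no call, with 723 genes at an unadjusted p under 0.05. The planned quantile normalisation is the one reported, since the deposited values were not equalised. Without background levels, the dimmest genes, such as Mir140, cannot be separated from background.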

Other observations

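The tests of marker lists against each other and of DPM replicate 3 below were chosen after the list scores had been seen. The counts over other splits of the arrays were planned before.

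Markers of fat, muscle and squamous epithelium differed widely between tumours of the same group. Adipocyte marker scores ranged from -0.516 in DPM replicate 3 to 1.033 in DPM replicate 1. DPM replicate 1 also had the highest skeletal muscle (0.363), squamous (0.471) and endothelial (0.229) scores. Cell cycle genes were lowest in vehicle replicate 1 (-0.164) and highest in vehicle replicate 2 (0.180), the tumour with the lowest milk protein score. Wwp2, the gene that hosts Mir140 in its intron and was looked up after Mir140 had been seen, averaged 10.09 ± 0.24 in DPM and 10.89 ± 0.28 in vehicle tumours, a difference of -0.80 (SE 0.17, n = 3 each, limma adjusted p = 0.904). Amtn, an ameloblast protein gene also chosen after its value was seen, had the largest difference of any gene, -1.76 (SE 0.34, limma adjusted p = 0.817). Among the 13767 probe sets that name several genes or none, limma called 0, with 323 at an unadjusted p under 0.05.

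The count of gene lists called was not the highest in the real split. For the count of genes, other splits decide nothing: the real split called 0, so all 10 of the 10 splits must call at least as many. For the count of gene lists, the real split called 12 and the highest of the others 16, with 3 of the 10 splits at 12 or more. With 10 splits no share can fall under 0.05. The extracellular matrix list was called in 8 of the 9 other splits, fibroblast markers in 7, the interferon, milk, endothelial and macrophage lists in 4 each, the fatty acid and inflammatory lists in 2 each, the nucleoside, epithelial to mesenchymal transition and basal lists in 1 each and oxidative phosphorylation in 0. One hypothesis is that lists whose genes vary together between tumours are called with a preset correlation whichever arrays are grouped. The estimated correlations were 0.424 for the matrix list, 0.770 for fibroblast markers and 0.505 for interferon genes. Among the 12 lists, those with estimated correlations of 0.29 or more were called in 4 to 8 of the 9 other splits. Those with 0.112 or less were called in 0 to 2. Among the former, the counts did not rise steadily with the correlation. Endothelial markers (0.602) and macrophage markers (0.426) were called in 4 other splits each, against 8 for the matrix list. The matrix list also had more members measured, at 40 against 13 and 16. The correlations were -0.00107 for basal markers and 0.000189 for the nucleoside list. The latter pair lie below the preset 0.01, yet the basal and nucleoside lists lost their calls under the estimated form as well (0 lists called). For basal markers the unadjusted camera p was 1.52e-06 with the preset and 0.00703 with the estimated correlation. For the nucleoside list it was 0.00107 and 0.0235. These values argue against correlation between genes as the reason why these lists lost their calls. The estimated form also uses the few residual degrees of freedom, which the preset form does not.

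For the lower basal and myoepithelial markers, the real split shifted the score by -0.247 and the highest other split by 0.183 in size. That makes 1 of 10 splits, the real one, and 10 are too few for a share under 0.05. A lower share of every cell type other than luminal epithelium is argued against by pericyte markers: the basal shift minus the pericyte shift was -0.332 (SE 0.0745, 95% interval -0.607 to -0.0574, shared genes left out). Against endothelial markers it was -0.365 (interval -0.688 to -0.0416), while fibroblast markers were too variable to decide (0.0309, interval -1.24 to 1.31). These intervals allow neither for several comparisons nor for the choice of the basal list after its shift was seen, so the argument is weak. A lower content of basal cells, lower expression within them, and an effect of DPM on either may each account for the pattern and were not tested.

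For the lower interferon genes, 2 of the 10 splits shifted the score by at least as much as the real one (-0.461, highest other 0.475 in size). Whether the DPM tumours held fewer macrophages and dendritic cells stays open. The interferon shift exceeded the mean shift of their markers by -0.310 (SE 0.134), with a 95% interval from -0.691 to 0.0718 that reaches 0, so such a loss of cells cannot be told apart from lower expression with 3 tumours per group. Without both arrays numbered 3, interferon genes stayed lower (mean -0.407) while macrophage and dendritic markers had means of 0.00982 and -0.0231, on 2 tumours per group. Without DPM replicate 1 all were lower together, with means of -0.634 for interferon genes, -0.271 for macrophage and -0.272 for dendritic markers. These subsets point different ways and do not decide whether such a loss occurred. An effect of DPM itself was not tested apart from these.

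For the lower extracellular matrix genes, whether DPM replicate 3 alone carries the call stays open. Without it the list was not called (camera adjusted p = 0.074, mean -0.0822 against -0.238), but without both arrays numbered 3 it was (adjusted p = 0.0318, mean -0.0934). The list's scores were -0.009, 0.072 and -0.42 on the DPM arrays and 0.061, 0.201 and 0.095 on the vehicle arrays. The preset form called the list in 8 of the 9 other splits as well, so keeping or losing that call decides little. Over the other settings with the preset correlation its adjusted p ran from 5.89e-15 to 0.074. Of the 10 splits, 2 shifted the score as far as the real one (highest other 0.245 in size). Whether that tumour piece held less stroma than the others, or was sampled differently, was not tested.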
